A study of Mus musculus with 5 samples.

How the data were processed

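RNA was measured by sequencing in 5 libraries of cells freshly sorted from the pancreas of adult C57BL/6 mice, 2 of CD133(positive)CD71(negative) cells and 3 of CD133(high)CD71(low) cells. CD133 is the surface protein encoded by Prom1, and CD71 is the transferrin receptor encoded by Tfrc. Groups were taken from the sample titles. Libraries 1 and 2 of each group carry a number in the title, and the third CD133(high)CD71(low) library, whose title has no number, is called library 3 here. Nothing in the labels says whether the libraries of a group came from separate animals or sorts, so p-values measure only the spread between these libraries, which may be technical.

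The authors deposited one table per library with one value per gene symbol. Per the submitters' processing notes, Partek and the mm10 genome were used, and the version of Partek, the aligner and the gene annotation are not given in the sources used here. No label states the unit. The deposited values behaved as RPKM, reads per kilobase of transcript scaled to library depth. Low values multiplied by transcript length fell on whole multiples of one step per library. RPKM cannot be told apart from FPKM in this way. The steps gave depths of 25.4 and 19.8 M reads (M, 1e6) for the CD133(positive)CD71(negative) libraries and 32.0, 30.8 and 41.9 M for the CD133(high)CD71(low) libraries. Between 52.1% and 57.5% of the low values tested lay within 0.05 reads of a whole number, against 10.0% by chance. This was too few to turn the tables back into counts, so tests made for counts were not run. The step finder was tested on simulated data. The table of library 3 also lists 74.2 M alignments in a row that names no gene, which was left out.

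The 4 numbered libraries share one set of 18618 gene symbols and the table of library 3 holds 22522, so its gene models differ, and 16992 symbols common to all tables were used. Some symbols had been turned into dates, 24 of them in each numbered library and 23 in library 3. They were kept as they stand and none is named. Before averaging, replicates were compared: the variance between libraries over that expected from sampling reads was 3.3 for the CD133(positive)CD71(negative) libraries and 3.5 for CD133(high)CD71(low) libraries 1 and 2, so none was counted as a duplicate. It was 41.0 and 31.0 for library 3 against libraries 1 and 2.

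Values were transformed as log2(RPKM + 1), with a pseudocount of 1, and genes with a mean of at least 1 over the fitted libraries were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, group as the sole term) with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Gene lists with at least 5 tested members were tested with limma's camera with a preset correlation between genes of 0.01 and again with an estimated correlation. A simulation of the 5 libraries with 200 changed genes among 11769 recovered 76% of log2 changes of 2 and 38% of log2 changes of 1, with 5.8% of calls false. With the 4 numbered libraries (11695 genes) it recovered 95% and 76%, with 1.2% of calls false. The simulated noise was independent between genes and alike in all libraries. These rates therefore do not cover deviations shared across genes, such as those of library 3, and may not hold for the real libraries. With 2 libraries against 3, an exact permutation test on the ranks of a single value cannot go below a two-sided p of 0.2, so none was used.

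The test, the alternatives, the 23 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Prom1 and Tfrc; the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5, no overlap between groups and a symbol that is not of a predicted or small RNA gene; for each list with at least 3 tested members up to 2 risen and 2 fallen members with the smallest adjusted p (ties by p), or the 2 highest members if none passed; and the 5 highest genes of each group. It gave 79 genes, not all of which are named in the text, and other genes named were chosen after their values were seen. Of the 79, 76 were found by symbol in the GENCODE annotation of mm10, from which positions are given.

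The alternatives were a pseudocount of 0.1, no filter beyond a value above 0, a mean of at least 5, median-of-ratios scaling, quantile normalization, each library left out, and the replicate number as a block. Added after seeing the data were the 4 numbered libraries with median-of-ratios scaling, the same libraries with all genes of their own tables, a correction for GC content, removal of acinar genes with rescaling, without and with the amylase copies Amy2a2, Amy2a3 and Amy2a4, and recounts of list members under these library and scaling choices. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.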

Results

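The series compared the transcriptomes of 2 cell populations sorted from adult mouse pancreas, CD133(high)CD71(low) cells (3 libraries) and CD133(positive)CD71(negative) cells (2 libraries). Per its title, the series concerns enrichment of colony-forming progenitor cells in the CD133(high)CD71(low) fraction. Values are those deposited, with RPKM as the inferred unit. They are given as mean ± SD with n = 2 for CD133(positive)CD71(negative) and n = 3 for CD133(high)CD71(low). Fold changes are CD133(high)CD71(low) minus CD133(positive)CD71(negative) on the log2(RPKM + 1) scale. Depth was 19.8 to 41.9 M reads (M, 1e6) per library. Library 3 of CD133(high)CD71(low) was deposited with other gene models than the other 4. It stood apart from libraries 1 and 2 of its group (Pearson r across genes of 0.957 and 0.961, against 0.996 between libraries 1 and 2).

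CD133(high)CD71(low) cells held far lower levels of leukocyte and endothelial transcripts, moderately lower levels of mesenchymal and moderately higher levels of duct epithelial transcripts than CD133(positive)CD71(negative) cells. The summed RPKM of the leukocyte list was 1974 and 1961 in the CD133(positive)CD71(negative) libraries and 101.0, 87.5 and 52.9 in the CD133(high)CD71(low) libraries. That of the endothelial list was 1151 and 1067 against 336.3, 220.1 and 150.3. The mesenchymal and stellate list summed to 464.3 and 442.5 against 211.7, 193.5 and 202.5. The ductal list summed to 6202 and 6670 against 9742, 9725 and 12878. Of 11769 genes tested with limma, 735 were higher and 850 lower in CD133(high)CD71(low) cells at an adjusted p under 0.05. The falls were the larger: 255 genes fell and 3 rose by at least 4-fold. The groups did not overlap in 70.2% of genes, against 20% expected by chance. Genes moved together, with a median log2 fold change of 0.31, so this contrast is not a test. The number of higher genes depended on library 3 and on scaling. Without library 3, 4785 genes were higher and 1425 lower, so that 77.1% of calls were higher in place of 46.4%. Median-of-ratios scaling, which moved the median log2 fold change of all genes from 0.31 to 0, left 198 higher and 1173 lower (14.4% higher). With both changes 1315 were higher and 2177 lower (37.7% higher). Leaving out CD133(high)CD71(low) library 1 or 2 left 89 or 40 higher and 784 or 561 lower genes. Leaving out CD133(positive)CD71(negative) library 1 or 2, so that the group had 1 library, left 0 or 1 higher and 157 or 154 lower. Of the genes picked by the fixed rule, 33 rose and 36 fell. With each library left out in turn, 0 of the 33 and 13 of the 36 remained called every time.

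**Figure D1:**
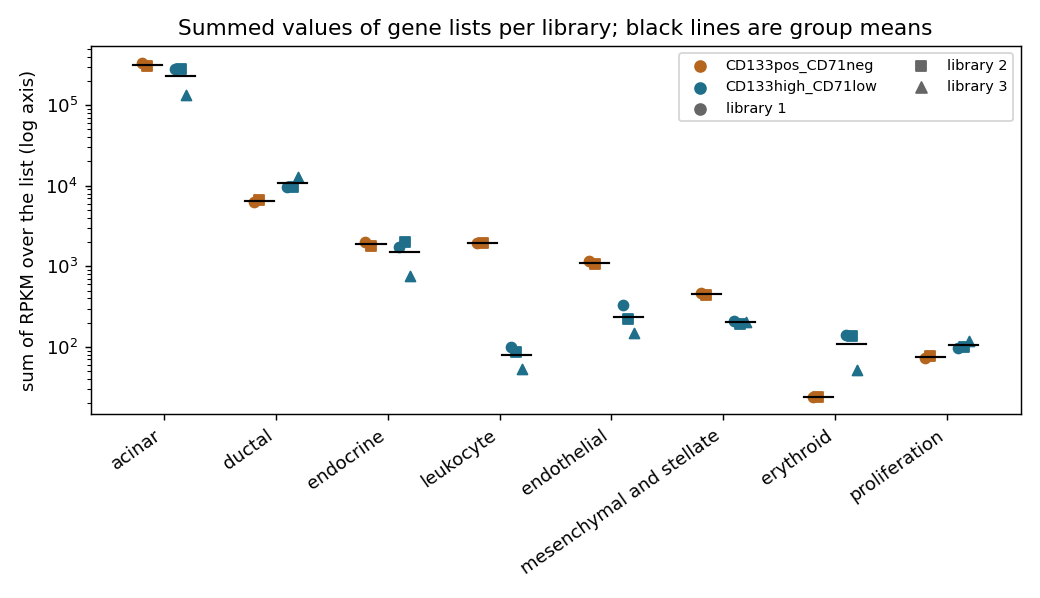
Summed RPKM (log axis) of 8 gene lists in each of the 5 libraries, with CD133(positive)CD71(negative) in brown, CD133(high)CD71(low) in blue, marker shape for the library number and black lines for group means. The leukocyte sums were 1974 and 1961 in CD133(positive)CD71(negative) and at most 101.0 in CD133(high)CD71(low), while the acinar sums were the highest in all 5 libraries.

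The genes of both sorting markers had higher means in CD133(high)CD71(low) cells, without passing the test over all 5 libraries. Prom1 (chromosome 5, 43993620 to 44102032, mm10), encoding CD133, measured 47.3 ± 2.14 in CD133(positive)CD71(negative) and 93.6 ± 34.4 in CD133(high)CD71(low), a log2 fold change of 0.91 (SE 0.29, limma adjusted p = 0.0909). Tfrc (chromosome 16, 32608920 to 32632794), encoding CD71, measured 4.18 ± 0.26 and 8.13 ± 3.61 (log2 fold change 0.75, SE 0.32, limma adjusted p = 0.151). Every CD133(high)CD71(low) library lay above both others for either gene, and library 3 was the highest, at 133.3 for Prom1 and 12.2 for Tfrc. Without library 3 both genes passed (limma adjusted p = 0.000208 and 0.0112). Adjusted over the list alone, 1 of the 2 rose.

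Most duct epithelial genes rose. Of 29 tested members of the ductal list 20 rose and 0 fell (24 rose when adjusted over the list alone), with a median log2 fold change of 0.82 (camera adjusted p = 4.7e-06, and adjusted p = 0.394 with an estimated correlation). Krt19, a keratin of duct cells, rose from 78.0 ± 4.79 to 149 ± 6.86 (log2 fold change 0.92, SE 0.12, limma adjusted p = 0.0089). Pkhd1, encoding the ciliary protein fibrocystin, rose from 23.5 ± 1.91 to 46.1 ± 3.96 (log2 fold change 0.94, limma adjusted p = 0.0105). Chosen after their values were seen, the duct transcription factor gene Sox9 (40.3 to 75.0) and the epithelial adhesion genes Epcam (106.6 to 185.5) and Cdh1 (138.3 to 259.1) were among the 20. The median of all genes was itself at 0.31. Under median-of-ratios scaling the ductal median was 0.47 and 5 members rose. With this scaling and without library 3 it was 0.50 and 25 rose. The ductal calls did not hold with each library left out in turn. Without a CD133(positive)CD71(negative) library almost all higher calls of any gene were lost, so that part does not speak on this list. Without CD133(high)CD71(low) library 1 or 2 the limma adjusted p was 0.0468 or 0.0484 for Krt19 and 0.0356 or 0.0503 for Pkhd1. In the duct ion transport list 2 of 19 members rose and 1 fell (11 rose and 2 fell when adjusted over the list alone, and 12 and 2 without library 3; camera adjusted p = 0.602). The carbonic anhydrase gene Car2 (13.6 ± 1.08 to 25.1 ± 3.95) and the potassium channel gene Kcnn4 (30.8 ± 3.41 to 44.2 ± 1.01) rose. Car4 fell from 4.52 ± 0.64 to 1.10 ± 0.23.

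Among the 8 largest rises, the laminin chain gene Lamc3 (chromosome 2, 31887291 to 31946539) rose from 4.18 ± 0.17 to 15.9 ± 4.15 (log2 fold change 1.68, SE 0.21, limma adjusted p = 0.00825). Ppp1r1b (chromosome 11, 98348404 to 98357796), encoding a phosphatase inhibitor, rose from 80.1 ± 8.04 to 199 ± 9.89 (log2 fold change 1.30, SE 0.13, limma adjusted p = 0.00394). The metalloproteinase gene Adam33 rose from 18.3 ± 2.42 to 46.7 ± 8.81 and the acyl-CoA thioesterase gene Acot1 from 12.1 ± 2.04 to 32.1 ± 11.4. The glucose transporter gene Slc2a2 rose from 5.40 ± 0.041 to 14.6 ± 2.94 and Cttnbp2 from 3.10 ± 0.18 to 8.91 ± 2.46. The other two were hemoglobin genes, Hbb-b1 (0.67 ± 0.82 to 9.66 ± 2.31) and Hba-a2 (6.17 ± 0.047 to 36.7 ± 17.9). They share near-identical sequence with their copies and are uncertain as single genes. In the erythroid list 4 of 5 tested members rose and 0 fell (4 when adjusted over the list alone; median 2.18; camera adjusted p = 0.0362, and adjusted p = 0.327 with an estimated correlation), including Hbb-b2 (0.23 ± 0.18 to 4.26 ± 2.06). With median-of-ratios scaling 2 of the 5 rose, and without library 3 all 5, as with both changes. The fifth, Hba-a1, measured 4.83 and 4.03 in the CD133(positive)CD71(negative) libraries and 58.5, 57.9 and 3.18 in the CD133(high)CD71(low) libraries. The erythroid list held 18 genes, of which these 5 were tested. Hbb-b1, Hbb-b2, Hba-a1 and Hba-a2 may share reads with their copies, so they are not separate support for the list.

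Leukocyte genes made up most of the largest falls. H2-Ab1 (chromosome 17, 34257689 to 34269419), encoding a chain of MHC class II, fell from 271 ± 8.65 to 6.13 ± 2.51 (log2 fold change -5.33, SE 0.33, limma adjusted p = 0.000732). H2-Aa fell likewise, at 265 ± 13.1 against 6.37 ± 2.22, and H2-Eb1 at 188 ± 1.88 against 4.33 ± 1.13. The lysozyme genes Lyz2 (294 ± 18.6 against 9.75 ± 4.02) and Lyz1 (71.9 ± 5.43 against 0.94 ± 0.61) fell as well. So did the immunoglobulin joining chain gene Igj (98.1 ± 18.4 against 2.15 ± 1.28) and the macrophage gene Retnla (114 ± 3.81 against 2.36 ± 1.44). The largest fall of all, Klk1b24 (131 ± 5.36 against 1.09 ± 0.44, log2 fold change -6.01), belongs to a family of near-identical kallikrein genes and is uncertain. Of 22 tested members of the leukocyte list 21 fell and 0 rose (22 fell when adjusted over the list alone). The median log2 fold change was -3.71 (camera adjusted p = 1.56e-37, and adjusted p = 0.221 with an estimated correlation). The lysosomal genes Laptm5 (39.8 ± 0.47 against 1.31 ± 0.20) and Ctss (39.7 ± 3.74 against 0.89 ± 0.31) had the smallest p before adjustment. Csf1r did not pass, at 20.03 ± 0.84 and 14.9 ± 1.00. With each library left out in turn, 17 of the 21 remained called every time.

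Endothelial and mesenchymal genes fell less steeply. Of 20 endothelial members 19 fell and 0 rose (19 when adjusted over the list alone). The median was -2.38 (camera adjusted p = 4.75e-21, and adjusted p = 0.31 with an estimated correlation). Emcn, encoding endomucin, fell from 26.9 ± 2.59 to 3.27 ± 1.51 (log2 fold change -2.77, limma adjusted p = 0.00586). Egfl7 fell from 62.6 ± 1.76 to 19.5 ± 2.89 (log2 fold change -1.64, limma adjusted p = 0.00291). Ecscr measured 32.8 ± 2.23 and 37.4 ± 9.52 and did not pass. Of 19 mesenchymal and stellate members 13 fell and 0 rose (15 fell when adjusted over the list alone). The median was -1.59 (camera adjusted p = 1.49e-16, and adjusted p = 0.221 with an estimated correlation). Fn1, encoding fibronectin, fell from 41.7 ± 1.54 to 6.28 ± 2.25 and the collagen gene Col1a1 from 5.62 ± 0.40 to 0.61 ± 0.42. Of the Schwann cell list 3 of 6 members fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00182, and adjusted p = 0.368 with an estimated correlation). Gfra3 (5.55 ± 1.196 to 0.061 ± 0.040) and Sox10 (2.71 ± 0.26 to 0.12 ± 0.016) fell. The receptor gene Erbb3 rose (14.8 ± 0.45 to 26.6 ± 1.80). Of 3 mesothelial members 1 fell, Igfbp6 (4.47 ± 0.21 to 0.43 ± 0.24), also when adjusted over the list alone. With each library left out in turn, 0 of these endothelial and mesenchymal members stayed called every time. Without CD133(positive)CD71(negative) library 1 or 2 the limma adjusted p of Emcn was 0.12 or 0.1.

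**Figure D2:**
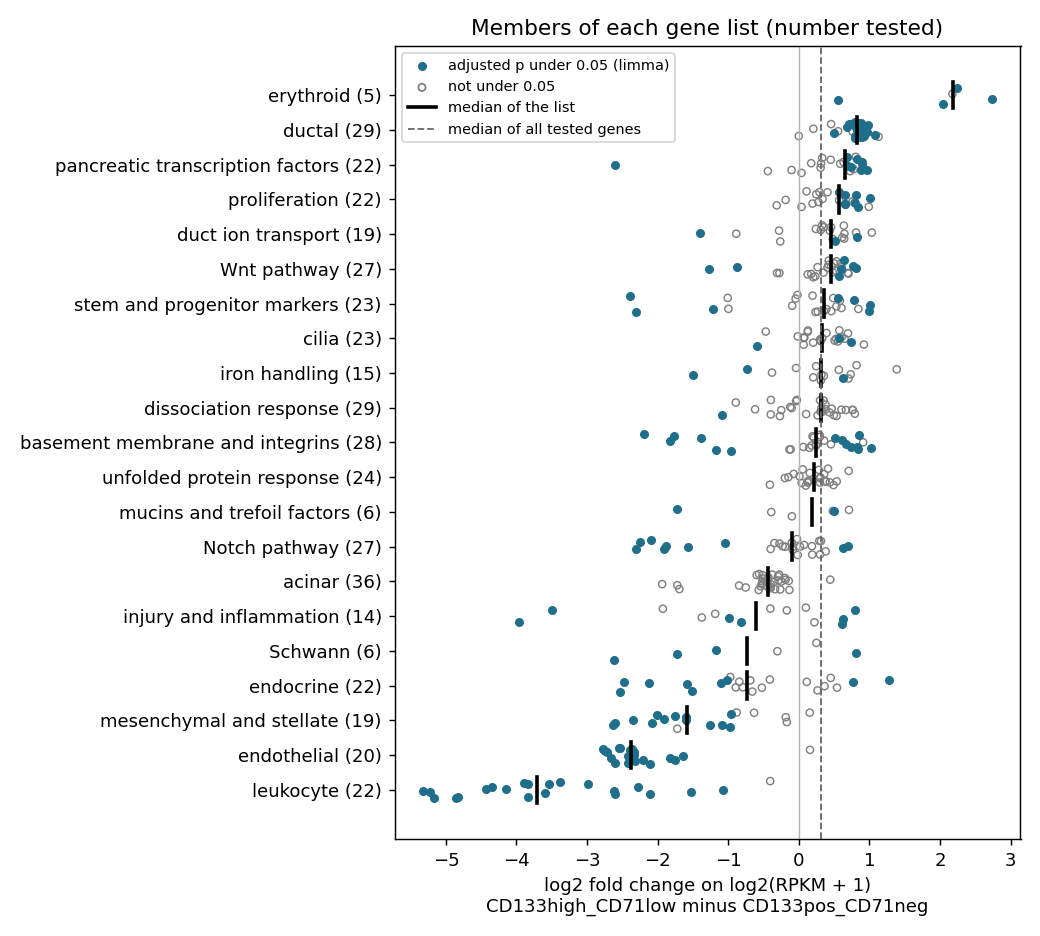
Each point is a tested member of a gene list (number tested in brackets), placed by its log2 fold change on log2(RPKM + 1), CD133(high)CD71(low) minus CD133(positive)CD71(negative). Filled points had a limma adjusted p under 0.05, black bars are list medians, and the dashed line is the median of all tested genes, 0.31. The leukocyte list had the lowest median, -3.71, and the erythroid list the highest, 2.18.

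Acinar digestive enzymes gave the most abundant transcripts in the libraries of both populations. In limma 0 of 36 tested members of their list passed in either direction (0 when adjusted over the list alone), against 9 that fell and 0 that rose without library 3. Their list took 63.3% and 60.0% of the RPKM of the common genes in the CD133(positive)CD71(negative) libraries and 55.5%, 56.2% and 31.5% in the CD133(high)CD71(low) libraries. The median log2 fold change was -0.44, and -0.18 without library 3 (camera adjusted p = 2.89e-08 with all libraries, and adjusted p = 0.545 with an estimated correlation). The pancreatic amylase gene Amy2a5 measured 76960 ± 8190 and 50920 ± 29547, with 16839 in library 3, where its near-identical copies Amy2a2, Amy2a3 and Amy2a4 were each at 15135. These copies are not in the list, and with them its share in library 3 was 42.1% of the common genes and 36.7% of the whole table. The chymotrypsinogen gene Ctrb1 measured 39596 ± 1789 and 28486 ± 10899. The limma adjusted p was 0.429 for Amy2a5 and 0.438 for Ctrb1. The other most abundant genes were Cela2a, Cela1, Try4 and Pnlip. Whether the sorted cells made the acinar transcripts or these came from other cells was not tested. Of 22 endocrine members 7 fell and 2 rose (12 and 4 when adjusted over the list alone; median -0.74; camera adjusted p = 2.52e-07, and adjusted p = 0.368 with an estimated correlation). The peptide hormone gene Pyy fell from 65.6 ± 5.96 to 14.5 ± 3.60 (log2 fold change -2.13, limma adjusted p = 0.00485). Slc2a2 and Ttr (56.4 ± 0.79 to 97.3 ± 17.0) rose. Without library 3, 12 fell and 6 rose, the latter including the insulin genes Ins1 (log2 fold change 0.95, limma adjusted p = 0.00245) and Ins2 (log2 fold change 0.85, limma adjusted p = 0.00142), whose groups overlapped with library 3 included.

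Among transcription factors of the pancreas 8 of 22 members rose and 1 fell (12 and 1 when adjusted over the list alone). The median was 0.66 (camera adjusted p = 0.0743, and adjusted p = 0.589 with an estimated correlation). The list was called without library 3 (camera adjusted p = 0.0163, and adjusted p = 0.753 with an estimated correlation) and under median-of-ratios scaling (camera adjusted p = 0.00633), where its median was 0.31, against 0.36 with both changes. Glis3 rose from 14.6 ± 1.81 to 29.5 ± 2.19 and Foxa2 from 22.1 ± 1.94 to 36.0 ± 2.14. Id3 fell from 58.6 ± 3.91 to 10.2 ± 6.36. Under median-of-ratios scaling 4 rose, without library 3 15, and with both changes 12. Of 23 stem and progenitor markers 4 rose and 3 fell (7 and 4 when adjusted over the list alone, and 10 and 7 without library 3). The median was 0.36, against 0.13 without library 3, 0.06 under median-of-ratios scaling and -0.06 with both changes, and camera gave an adjusted p of 0.602. Dclk1, a marker of tuft cells, rose from 1.05 ± 0.023 to 2.52 ± 0.13 and the retinaldehyde dehydrogenase gene Aldh1a1 from 20.9 ± 0.042 to 43.5 ± 7.86. The chemokine receptor gene Cxcr4 fell from 15.4 ± 0.84 to 2.46 ± 1.21 and Klf4 from 18.2 ± 1.10 to 7.35 ± 1.48. The leukocyte and endothelial sums were 24.45 and 4.71 times as high in CD133(positive)CD71(negative) as in CD133(high)CD71(low). Of 22 proliferation genes 8 rose and 0 fell, and 9 rose when adjusted over the list alone (camera adjusted p = 0.0688, and adjusted p = 0.589 with an estimated correlation). Camera with an estimated correlation was not run under median-of-ratios scaling. Under that scaling 2 rose and 0 fell (camera adjusted p = 0.00633), without library 3 10 and 1, and with both changes 8 and 2. The median was 0.57, and 0.32, 0.27 and 0.11 in these settings. The cyclin genes Ccnb2 (0.46 ± 0.14 to 1.95 ± 0.46) and Ccna2 (0.61 ± 0.026 to 1.89 ± 0.38) rose at low levels.

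Of 27 members of the Notch pathway list 7 fell and 2 rose (8 and 2 when adjusted over the list alone). Without library 3, 12 fell and 3 rose, under median-of-ratios scaling 11 and 0, and with both changes 14 and 3. The median of the list was -0.09, and -0.12, -0.42 and -0.35 in these settings, and its mean was -0.43 (camera adjusted p = 6.08e-05, and adjusted p = 0.221 with an estimated correlation). Mfng, a glycosyltransferase acting on Notch, fell from 5.16 ± 0.23 to 0.68 ± 0.28 (log2 fold change -1.88, limma adjusted p = 0.00258). The feedback regulator gene Nrarp fell from 12.7 ± 0.46 to 3.66 ± 0.79. The receptor gene Notch2 rose from 15.1 ± 0.74 to 24.0 ± 1.98 and Dtx4 from 7.202 ± 0.79 to 12.3 ± 1.41. The other fallen members, named after their values were seen, were Dll4, Notch4, Hey1, Jag2 and Lfng. Between the same groups the endothelial sum was 4.71 times as high in CD133(positive)CD71(negative). Within CD133(high)CD71(low) it was 336.3, 220.1 and 150.3. In the Wnt pathway list 5 of 27 rose and 2 fell (12 and 2 when adjusted over the list alone, and 16 and 4 without library 3; camera adjusted p = 0.316). Wnt4 rose from 16.4 ± 1.22 to 29.7 ± 1.94 and the receptor gene Fzd5 from 5.26 ± 0.49 to 9.62 ± 0.38. Fzd4 fell from 10.1 ± 0.39 to 3.60 ± 0.48 and Tcf7 from 2.05 ± 0.19 to 0.67 ± 0.065. Basement membrane and integrin genes moved both ways, with 8 of 28 risen and 6 fallen (9 and 6 when adjusted over the list alone, and 13 and 6 without library 3; camera adjusted p = 0.602). The integrin gene Itga3 rose from 14.9 ± 0.47 to 27.7 ± 1.86. Col4a2 fell from 39.2 ± 0.37 to 17.0 ± 2.25 and Nid2 from 3.73 ± 0.26 to 0.41 ± 0.33.

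Of 14 injury and inflammation genes 4 fell and 3 rose (the same numbers when adjusted over the list alone, and 6 and 3 without library 3), with camera adjusted p = 0.00164, and adjusted p = 0.221 with an estimated correlation. The cytokine gene Il1b (13.2 ± 0.19 to 0.26 ± 0.062) and the chemokine gene Ccl5 (17.2 ± 7.06 to 0.12 ± 0.059) fell. The leukocyte sum was 24.45 times as high in CD133(positive)CD71(negative) between the same groups. The injury and inflammation sums were 692.0 and 802.3 in CD133(high)CD71(low) libraries 1 and 2 and 184.7 in library 3. Cd14 (20.4 ± 1.41 to 36.1 ± 1.31) and C3 (19.6 ± 0.19 to 30.7 ± 1.94) rose. Of 15 iron handling genes 1 rose and 2 fell (5 and 2 when adjusted over the list alone, and 7 and 2 without library 3; camera adjusted p = 0.901). Lcn2 rose (17.7 ± 0.16 to 27.9 ± 1.97), and Hmox1 (5.53 ± 0.19 to 1.34 ± 0.42) and Hfe (9.39 ± 0.30 to 5.25 ± 0.50) fell. Of 6 mucins and trefoil factors 1 rose and 1 fell (2 and 1 when adjusted over the list alone or without library 3; camera adjusted p = 0.418). Muc1 rose (81.1 ± 5.23 to 115 ± 2.84) and Gkn3 fell (4.62 ± 0.60 to 0.71 ± 0.28). Of 23 cilia genes 2 rose and 1 fell (4 and 1 when adjusted over the list alone, and 12 and 2 without library 3; camera adjusted p = 0.612). Ift122 (9.50 ± 0.65 to 16.6 ± 2.84) and Pkd2 (21.4 ± 2.99 to 32.0 ± 1.73) rose. Tppp3 fell (35.3 ± 0.75 to 23.1 ± 1.19). Of 29 genes responding to tissue dissociation 1 fell, Ier5 (13.5 ± 0.61 to 5.89 ± 1.25), also when adjusted over the list alone (camera adjusted p = 0.392). Without library 3, 14 rose and 5 fell. Of 24 unfolded protein response genes 0 passed with limma in either direction, also when adjusted over the list alone (camera adjusted p = 0.922). Without library 3, 8 rose and 1 fell. Calr measured 162 ± 3.68 and 213 ± 40.4, and Hspa5 measured 167 ± 16.8 and 207 ± 37.1.

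**Figure D3:**
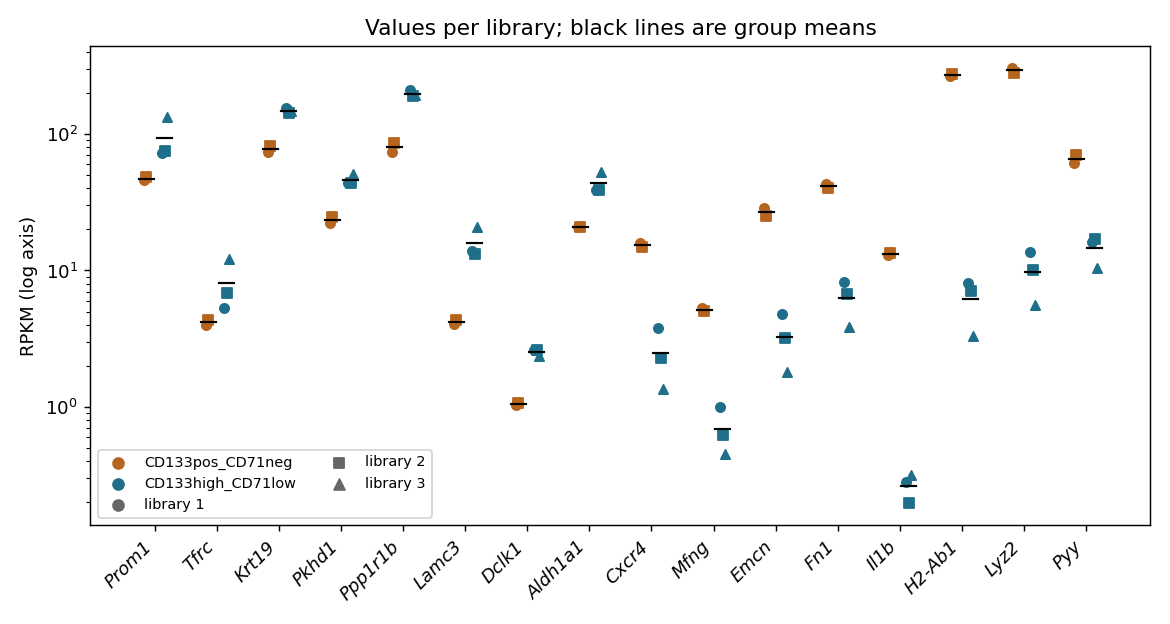
RPKM per library (log axis) of 16 genes, with CD133(positive)CD71(negative) in brown, CD133(high)CD71(low) in blue, marker shape for the library number and black lines for group means. Krt19 lay at 78.0 and 149 on average, Lyz2 at 294 and 9.75, and Prom1 was highest in library 3, at 133.3.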

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

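The tests in this part that bear on library 3 were chosen after its values were seen, except that on GC content. The gene Beta-s, a hemoglobin beta gene model found in the 4 numbered tables alone, lay outside the comparison and carried a clear signal: 6.50 and 4.28 RPKM in the CD133(positive)CD71(negative) libraries and 71.1 and 70.7 in CD133(high)CD71(low) libraries 1 and 2, a mean of 70.9 in the latter (log2 fold change 3.51, SE 0.14, limma adjusted p = 3.2e-07 in the fit of these tables). The limit that 0 reads allow for a transcript of 1 kb was at most 0.152 RPKM, for counting error only. The table of library 3 held 5530 symbols outside the common set, of which 1566 had at least 1 RPKM, and they summed to 12.7% of its values.

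Library 3 of CD133(high)CD71(low) was set apart from libraries 1 and 2 by an SD of the log2 difference of 0.64, against 0.18 between those libraries. Many ribosomal protein genes were near 0 in it (Rps12 at 1.36e-12, against 309.7 and 321.5), and the sum over 85 such genes was 0.50 of the mean of libraries 1 and 2. Adding the pseudogene rows of its own table raised that ratio to 0.94, so reads of these genes assigned to pseudogene rows may account for this part. They do not account for the whole, since outside ribosomal protein genes, pseudogenes and unnamed gene models the SD was still 3.22 times that between libraries 1 and 2, nor does a trend with GC content, since after its removal the ratio was 3.43. What else set library 3 apart stays open, as no label gives a batch, and no biological explanation was tested.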

How the results depend on the processing

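The added choices named here were made after seeing the data. Of 735 higher and 850 lower genes, median-of-ratios scaling gave 198 and 1173, the absence of a filter 1729 lower, and a mean of at least 5, which tests fewer genes, 505 and 315 (lower moved by over 1.5 times). Leaving out 1 library gave 0 to 4785 higher and 154 to 1425 lower genes; without a CD133(positive)CD71(negative) library the lone one was assumed to vary like the other group. Among the added settings, the 4 numbered libraries gave 1315 higher and 2177 lower with median-of-ratios scaling and 4780 and 1431 with all genes of their tables, GC correction 1285 higher, acinar removal 254 higher, and removal of the amylase copies too 431 higher. Apart from the replicate block, other settings stayed within 1.5 times, and the causes were not tested. The same-direction calls shared with the main result numbered 1583 of 1585 without library 3 and 1034 under median-of-ratios scaling, and none of the 1585 changed sign in any setting where it was tested.

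With the replicate number as a block, in the libraries numbered 1 and 2, 5275 genes were higher and 1543 lower, against 4785 and 1425 in the same libraries without it. Deviations from the group means of same-numbered libraries correlated at r = -0.02 across genes, which gave no sign of pairing. With 2 numbered libraries per group this cannot exclude that equal numbers pair the libraries, and no label says whether they do.

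Of the 79 named genes 0 were counted as reversed. A gene uncalled both in the main fit and in a setting counted as unchanged whatever its sign, so this speaks for called genes alone. Calls were lost for 18 under median-of-ratios scaling, 12 under quantile normalization, 54 and 52 without CD133(positive)CD71(negative) library 1 or 2, and 22 and 29 without CD133(high)CD71(low) library 1 or 2; 4 were gained without library 3. All 10 list calls were lost with an estimated correlation, and 0 with median-of-ratios scaling or without library 3, where 2 and 1 were gained. A larger correlation was not the whole reason for the loss. The estimate was -0.01 for the injury and inflammation list, yet its unadjusted camera p went from 0.000626 to 0.0358. For the erythroid list it was -0.1, and the unadjusted camera p went from 0.0172 to 0.0934. Depth limits genes near 1 RPKM most. Alternatives made for counts were not run, as the values are not counts.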

Other observations

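The lists in this part, and all tests except that on acinar mRNA, were chosen after the values were seen. The leukocyte transcripts were split by lineage. Of 17 tested macrophage and monocyte genes 15 were lower in CD133(high)CD71(low) cells (median log2 fold change -3.37), Cd14 was higher and Csf1r did not pass. Among the 15 were the chemokine receptor gene Ccr2 (14.3 ± 0.77 against 0.10 ± 0.01 RPKM, limma adjusted p = 0.000392) and the scavenger receptor gene Mrc1 (3.54 ± 0.44 against 0.20 ± 0.07). The 9 tested genes picked for dendritic cells were lower too (median -2.51), with Ccl22 at 12.6 ± 1.77 against 0.05 ± 0.01, Cd209a at 7.41 ± 0.35 against 0.02 ± 0.02 and Flt3 at 2.48 ± 0.15 against 0.02 ± 0.01. Of 10 T and NK cell genes 0 reached a mean of 1 RPKM over the 5 libraries, so none was tested. A gene present in CD133(positive)CD71(negative) alone can miss this mean, so absence of these cells is not shown. Of 7 B and plasma cell genes 3 were tested and fell, Cd79a, Cd79b and Igj.

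Among genes found in the 4 numbered tables alone, 49 were higher and 20 lower in CD133(high)CD71(low) of 190 tested with limma. The leukocyte gene Bin2 (4.18 ± 0.11 against 0.25 ± 0.04 RPKM) and the mesenchymal transcription factor gene Foxf1 (2.47 ± 0.26 against 0.54 ± 0.03) were lower, and the RNA gene Snhg5 (7.53 ± 0.71 against 12.1 ± 0.76) was higher.

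Genes with near-identical copies swung within groups. Prss1 measured 6.59 and 1188 in the CD133(positive)CD71(negative) libraries and 947.5, 5.26 and 3.02 in the CD133(high)CD71(low) libraries. Amy2a2 measured 26.9, 34.7, 21.5 and 25.4 in the numbered libraries and 15135 in library 3, where Amy2a5 was at 16839 against 66580 or more in the others. Apart from these copies, Xist, the RNA of the inactive X chromosome, measured 14.8 and 20.3 in the CD133(positive)CD71(negative) libraries. It measured 18.5, 27.3 and 93.2 in the CD133(high)CD71(low) libraries. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were found in the 4 numbered tables alone. Eif2s3y measured 4.30 and 4.27 in the CD133(positive)CD71(negative) libraries and 4.75 and 4.39 in CD133(high)CD71(low) libraries 1 and 2. Library 3 cannot be compared for these genes. Why Xist was highest in library 3 was not tested, and a difference of the animals used stays open.

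The lower leukocyte, endothelial and mesenchymal transcripts were weighed against the makeup of the sorted cells. One lower share of epithelial cells in CD133(positive)CD71(negative) would raise all other cell types alike, but the endothelial and leukocyte medians differed by 1.23 pooled SDs of their members. Leukocytes in the CD133(positive)CD71(negative) libraries were not tested as a source. Genes picked for macrophages and monocytes (15 of 17, with Cd14 higher), dendritic cells (9 of 9) and B and plasma cells (3 of 3) were lower together in CD133(high)CD71(low). These genes were picked after the values were seen. Those near 0 in CD133(high)CD71(low) were tested only through their level in the other group. Their common direction is therefore no test of a change within epithelial cells. In the leukocyte list, fixed beforehand, 21 of 22 tested members fell under the same filter. For leukocyte, endothelial and mesenchymal genes a difference of the sorted cells themselves stays open. The sort used CD133 and CD71, and no other gate is given. Whether leukocytes, endothelial or mesenchymal cells carried CD133 or passed the gate otherwise stays open.

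The 7 fallen Notch members may be carried by endothelial cells. Between CD133(high)CD71(low) libraries 1 and 2 their median log2 ratio was -0.30, outside the range of -0.13 to 0.09 that holds 95% of 10000 random gene sets, but more than 1 SD (0.18) from the endothelial median of -0.57. The direction goes with that explanation. The median falls short of it in size, but the log2(RPKM + 1) scale shrinks changes of low values. The fallen members were low in library 1, from 0.99 for Mfng to 7.45 for Jag2, so the size cannot decide. With 1 pair of libraries the explanation stays open, as does a difference of the sorted cells themselves.

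The median of all genes was 0.31 above 0. With acinar genes removed and libraries rescaled to the same total it was 0.05, and 0.12 when the amylase copies were removed too (added after seeing the data), on either side of the bound of 0.1 set before the acinar mRNA test.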
